A study of Mus musculus with 15 samples.

How the data were processed

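Messenger RNA from ear tissue of female mice aged 5 weeks was sequenced in 15 libraries, of which 5 were labelled control, 4 PMA_ethanol and 6 PMA_1002. PMA is phorbol 12-myristate 13-acetate, an irritant that activates protein kinase C and inflames skin, and the third group also received the innate defense regulator peptide named in the series title. Per the labels' protocols, polyA RNA was isolated and libraries were made with a strand-preserving kit. Per the submitters' processing notes, FastQC 0.11.5, MultiQC 0.8, STAR 2.5 and HTSeq were used with the GRCm38 build. The strand option of the counting and the annotation release are not given in the sources used here, so antisense and overlapping genes are uncertain. The deposited tables count reads with several positions apart from genes, from 15.98% of reads (control library 3) to 20.12% (PMA_ethanol library 3). Families of near-identical genes such as the Stfa, Sprr, Lce, Serpinb3 and Krtap genes may therefore be undercounted, and their values are uncertain.

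The deposited values are whole-number read counts per gene, one table per library, with 48795 genes and no normalization. The deposited tables also hold counts of reads given to no gene, 28.5% to 32.85% of the reads in each table, and these stayed out of library sizes and tests. Gene identifiers were paired with symbols and positions through GENCODE M21 on GRCm38, and 48349 of them had a symbol there. The genes without a symbol held 0.0913% of the reads in genes. Reads in genes ran from 2656680 (PMA_ethanol library 3) to 28585995 (PMA_1002 library 5).

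Groups came from the sample titles. The gene lists, the rule for naming genes, the tests and the alternatives listed as planned were chosen before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM scaling, filterByExpr by group (14991 genes tested) and robust quasi-likelihood fits over all 15 libraries with the 3 groups as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold. A standard error (SE) of a log2 fold change was derived from the quasi-likelihood F statistic. CPM are counts-per-million values relative to the TMM-scaled library size, and logarithms of CPM used a prior count of 2. The common biological coefficient of variation was 0.185. Libraries of 1 group were compared over genes with at least 10 reads, and chi-square per degree of freedom lay between 2.927 and 27.02 over the 31 pairs, so no library was treated as a repeat of another.

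Gene lists, 31 in all, were written from textbook knowledge. Each was tested in 3 ways. Members called by edgeR were counted, over all genes and adjusted over the list alone. The level of a list in a library, the mean log2 CPM of its measured members, was compared between groups with a two-sided exact permutation test, adjusted over the lists within a comparison, in which the smallest adjusted p reached was 0.0123, 0.0114 and 0.00419 in the order of the comparisons in the report. Camera from limma 3.58.1 was run on voom values with a preset correlation of 0.01 and with an estimated correlation. Fry was run as an alternative.

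Genes are named in the text by 3 rules. A fixed panel of 16 genes is named whatever its result, except that some genes the rules name are not reported here. The largest changes are named among called genes whose groups do not overlap in CPM, with a mean of at least 5 CPM in the higher group and an assigned name, up to 8 per direction for the first 2 comparisons and 4 for the last. Up to 3 called members of each list, those with the smallest adjusted p, are named per comparison, and up to 2 members where none was called. A gene outside these rules is said to be chosen after its values were seen.

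The share of the PMA change left with the peptide was estimated on libraries held out from the choice of genes. Genes were called between 3 control and 2 PMA_ethanol libraries, and the changes of those genes were measured with the other control and PMA_ethanol libraries, over all 60 such splits. Overlaps between comparisons that share libraries are given with 20 simulations without any effect, with the overlap of independent lists, and with the shared libraries split between the comparisons. For genes apart from both other groups in PMA_1002, 20 more simulations placed each gene of PMA_1002 at the estimated share of its log change with PMA_ethanol. Where a group held 0 reads of a gene, the fold is a lower bound against a floor of 3 reads over the group, and with 1 to 3 reads a ratio is given with its exact 95% binomial interval. These intervals and floors cover counting error only.

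The gene test, the camera list test and the estimate of the remaining share were tested on simulated data drawn from the mean of the control libraries and from the dispersions and depths of all 15 libraries, over 14991 genes. For PMA_ethanol versus control, 38.8%, 65.7% and 98.5% of genes changed by folds of 1.5, 2 and 4 were called, with 10 unchanged genes called. For PMA_1002 versus PMA_ethanol these were 59.7%, 82.1% and 92.4%, with 7 unchanged genes called, and for PMA_1002 versus control 43.3%, 88.1% and 97%, with 4. In each comparison 3 of 3 lists moved by a fold of 2 were called. A simulated remaining share of 0.6 was estimated at 0.612, from 3 of the 60 splits. In the gene test only 67, 67 and 66 genes changed by the 3 folds, and in the list test only the members of the 3 lists. These 2 tests therefore did not cover scaling under a broad change. Genes were drawn independently, so correlation between genes was not covered either.

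Alternatives were DESeq2 1.42.0, limma-voom with sample weights, RLE and upper-quartile scaling, no filter and a stricter filter on low counts (1 CPM in 4 libraries), a fit without robust dispersions, fits on the compared groups alone, a minimum fold of 1.5, the replicate number as a block, muscle and hair follicle levels as covariates, lists without the members they share, a prior count of 0.5, and leaving out each library in turn. A comparison with every library thinned to the depth of the shallowest, and one without the 6 libraries of the highest hair follicle level, were added after the data had been seen.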

Results

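Ear tissue of female mice in a model of skin inflammation was profiled by RNA sequencing in 3 groups: control (n = 5 libraries), PMA_ethanol (n = 4) and PMA_1002 (n = 6). The irritant phorbol ester PMA activates protein kinase C, ethanol is named in the label of the second group, and the third group also received the innate defense regulator peptide of the series title, whose anti-inflammatory action in sterile inflammation the study addressed. Doses, times and whether control ears received a vehicle are not given in the sources used here. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. Reads in genes numbered 5434288, 5371961, 11501228, 6042856 and 5654812 in control libraries 1 to 5. They numbered 10348634, 23999666, 2656680 and 7553257 in PMA_ethanol libraries 1 to 4. In PMA_1002 libraries 1 to 6 they numbered 9969723, 10057729, 5045243, 4958387, 28585995 and 5775609. All adjusted p-values of genes below come from two-sided edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment over 14991 genes. Fold changes are log2 values with their standard errors (SE), and CPM are means ± SD over the libraries of a group. All permutation tests of list levels are exact and two-sided.

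The 3 groups separated on the first principal component of log2 CPM, which held 60.3% of the variance. Control libraries scored between -79.3 and -69.5, PMA_1002 libraries between 2 and 25.1, and PMA_ethanol libraries between 61.6 and 93. Hair follicle genes weighed on the second component (17.1% of the variance), where 22 of the 26 measured members of the hair follicle list were among the 100 genes of largest weight. The hair follicle level varied within each group, from 1 to 6.62 log2 CPM in control, from -0.788 to 6.62 in PMA_ethanol and from -0.752 to 5.02 in PMA_1002. Skeletal muscle genes, which ear tissue also contains, had levels of 6.56 ± 0.619, 6.37 ± 1.01 and 6.32 ± 0.467 log2 CPM in control, PMA_ethanol and PMA_1002. The 10 most abundant genes of a library took 8.254% of the reads in control, 5.044% in PMA_ethanol and 7.031% in PMA_1002, and each pair of groups differed (exact permutation p = 0.00794, 0.00476 and 0.00649 for PMA_ethanol versus control, PMA_1002 versus PMA_ethanol and PMA_1002 versus control). The first 2 of these p-values are the smallest that the permutations can give.

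**Figure D1:**
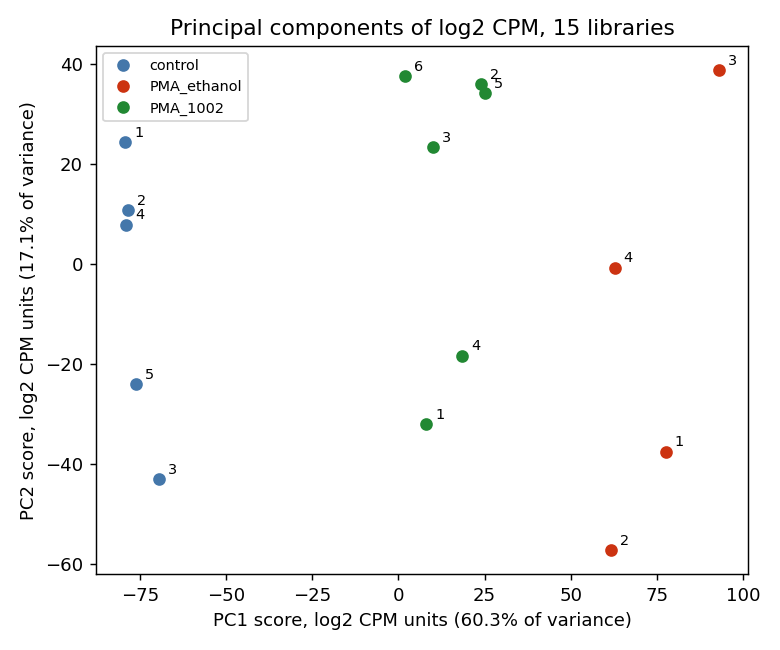
Each point is a library, numbered by its replicate, with its scores on the first (60.3% of variance, x axis) and second (17.1%, y axis) principal components of log2 CPM. PMA_1002 libraries lie between 2 and 25.1 on the x axis, between the control and the PMA_ethanol libraries.

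PMA_ethanol versus control asked how the irritant changed the ear transcriptome. Cxcl1, Il1b and Il6 rose, while 14 of 24 measured chemokine and 16 of 26 measured cytokine genes already had a control mean of at least 1 CPM. Cxcl1, a neutrophil-attracting chemokine, went from 0.995 ± 0.42 CPM in control (n = 5) to 246 ± 69.5 in PMA_ethanol (n = 4), a log2 fold change of 8.01 (SE 0.308, edgeR adjusted p = 8.02e-12). Il1b, the interleukin-1 beta gene, rose by 8.67 (SE 0.285, edgeR adjusted p = 9.88e-13), and Il6, an acute-phase cytokine, by 9.30 (SE 0.439, edgeR adjusted p = 8.59e-11). Krt10, a keratin of differentiating epidermis, fell from 13320 ± 1900 to 6210 ± 692 CPM, a log2 fold change of -1.10 (SE 0.112, edgeR adjusted p = 1.72e-07). In all, 4876 genes rose and 5382 fell, 68.4% of those tested, and 2072 and 2070 of them changed by a fold of at least 2.

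On GRCm38, Cxcl1 (ENSMUSG00000029380) lies on chromosome 5 from 90891241 to 90893115, near Cxcl2 (ENSMUSG00000058427, 90903871 to 90905938 on the same chromosome). Il6 (ENSMUSG00000025746) lies on chromosome 5 from 30013114 to 30019981. Il1b (ENSMUSG00000027398) lies on chromosome 2 from 129364570 to 129371139. Krt10 (ENSMUSG00000019761) lies on chromosome 11 from 99385254 to 99389364.

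Inflammatory lists rose almost throughout. In the chemokine list 24 of 24 measured members rose (24 adjusted over the list alone), among them Ccl2, a monocyte attractant, by 6.70 (SE 0.279, edgeR adjusted p = 2.09e-11) and Ccl7, by 6.22 (SE 0.214, edgeR adjusted p = 8.41e-13). In the pro-inflammatory cytokine list 25 of 26 rose (25 adjusted over the list alone), and in the NF-kB target list 21 of 21 (21 adjusted over the list alone), with Bcl3, a regulator of NF-kB, at 5.32 (SE 0.13, edgeR adjusted p = 2.16e-14). Of 26 AP-1 and immediate-early genes 23 rose (23 adjusted over the list alone), of 21 chemoattractant receptors 19 rose and 1 fell (19 and 1 adjusted over the list alone), and of 18 neutrophil genes 16 rose (16 adjusted over the list alone). Only 18 of 25 neutrophil genes were measured, and 9 of the 18 had a control mean of at least 1 CPM. The others could pass the filter on low counts mainly through the groups with PMA, which favours a rise. Among the neutrophil genes Cxcr2, the receptor for Cxcl1 and Cxcl2, rose by 4.66 (SE 0.222, edgeR adjusted p = 7.19e-11), whereas Mpo, the myeloperoxidase gene, had a fold change of -0.47 (SE 0.287, edgeR adjusted p = 0.155). The Mpo value passed the test with upper-quartile scaling (edgeR adjusted p = 0.0404, in a range of 0.0376 to 0.391 over 27 alternatives). The level of each of these 6 lists was higher in all 4 PMA_ethanol libraries than in all 5 controls (exact permutation adjusted p = 0.0123, the smallest reached). Camera called the 6 lists higher with the preset correlation but not with an estimated one, where the chemokine, cytokine, NF-kB, receptor and neutrophil lists had adjusted p = 0.0536 with an estimated correlation and the AP-1 list adjusted p = 0.0571 with an estimated correlation.

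Tissue remodelling and adhesion genes rose too. Of 23 protease and matrix remodelling genes 22 rose (22 adjusted over the list alone), with Timp1, a metalloproteinase inhibitor, at 6.05 (SE 0.169, edgeR adjusted p = 4.94e-14). Of 14 endothelial activation and leukocyte adhesion genes 13 rose (13 adjusted over the list alone), with Icam1, a ligand of leukocyte integrins, at 3.97 (SE 0.168, edgeR adjusted p = 5.46e-12). These lists were the only 2 of the 31 that camera called with either correlation (adjusted p = 0.0182 with an estimated correlation for both). Of 28 keratinocyte wound and alarmin genes 26 rose (26 adjusted over the list alone; camera adjusted p = 0.303 with an estimated correlation). Among them Krt16, a keratin of wounded epidermis, rose from 17.2 ± 13 to 1979 ± 536 CPM, by 6.88 (SE 0.511, edgeR adjusted p = 5.45e-08), and S100a8, an alarmin, by 7.32 (SE 0.444, edgeR adjusted p = 5.62e-09). Several members of that list belong to families of near-identical genes, so their own values are uncertain. A control mean of at least 1 CPM was reached by 19 of the 28 measured members. The others could likewise pass the filter on low counts mainly through the groups with PMA. The median fold change of the wound list was 6.87, or 6.79 with the member without control reads at its bound.

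Interferon, myeloid and metabolic lists rose in part. Of 29 type I interferon-stimulated genes 19 rose and 2 fell (19 and 2 adjusted over the list alone), with Oasl2 at 2.80 (SE 0.234, edgeR adjusted p = 1.48e-08) and Irf7 at 1.82 (SE 0.294, edgeR adjusted p = 4.66e-05). The 2 that fell, Ifit2 and Ifit3, were named after their values were seen. The interferon-gamma list had 21 of 25 members higher and 1 lower (21 and 1 adjusted over the list alone), the monocyte and macrophage list 18 of 25 higher and 3 lower (18 and 3), the pattern recognition list 15 of 24 higher and 4 lower (15 and 4) and the oxidant list 15 of 24 higher and 4 lower (15 and 4). With the preset correlation camera called these 5 lists higher, but none with an estimated one, where the type I interferon list had adjusted p = 0.42 with an estimated correlation, the interferon-gamma list adjusted p = 0.369 with an estimated correlation, the monocyte list adjusted p = 0.307 with an estimated correlation, the pattern recognition list adjusted p = 0.0662 with an estimated correlation and the oxidant list adjusted p = 0.0536 with an estimated correlation. Their levels were higher with PMA_ethanol (exact permutation adjusted p = 0.0123 for each). Ptgs2, the inducible cyclooxygenase, rose by 6.75 (SE 0.339, edgeR adjusted p = 2.75e-10) within an eicosanoid list in which 13 of 23 members rose and 7 fell (13 and 7 adjusted over the list alone; camera adjusted p = 0.285).

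Most measured genes of the mast cell, Schwann cell and melanocyte, and cell cycle lists fell. Ms4a2, a chain of the mast cell IgE receptor, went from 21.5 to 1.88 CPM, by -3.45 (SE 0.286, edgeR adjusted p = 1.34e-08). In the mast cell list 9 of 13 members fell and 1 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.134), and the member that rose was Hdc, the histamine-forming enzyme that other myeloid cells also express (4.36, SE 0.17, edgeR adjusted p = 2.29e-12). In the Schwann cell and melanocyte list 15 of 17 fell (15 adjusted over the list alone; camera adjusted p = 0.015, and adjusted p = 0.369 with an estimated correlation), and Egr2, also an immediate-early gene, rose by 1.84 (SE 0.0686, edgeR adjusted p = 7.47e-13). In the cell cycle list 15 of 22 fell (16 adjusted over the list alone; camera adjusted p = 0.0464, and adjusted p = 0.703 with an estimated correlation), while Pcna and Rrm2, which act in DNA synthesis, rose by 0.58 (SE 0.0807, edgeR adjusted p = 7.13e-06) and 0.88 (SE 0.136, edgeR adjusted p = 1.95e-05). The levels of the 3 lists were lower with PMA_ethanol (exact permutation adjusted p = 0.0123 for each). In the terminal differentiation list of the epidermis 8 of 32 members rose and 9, among them Krt10, fell (8 and 8 adjusted over the list alone; camera adjusted p = 0.874), with a median fold change of -0.11 and a mean of 0.09, which differ in sign, and its level did not pass (exact permutation adjusted p = 0.828).

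By the fixed rule, which ranks fitted fold changes, Il24, Stfa1, Fgf23, Cxcl2, Acod1, Ccl4, Cxcl3 and Lpo were named for their rises. Stfa1 and Fgf23 had no read in the controls and were at least 106-fold and 210-fold higher, bounds (6.73 and 7.72 in log2) below the fold changes of Il6, Il1b and Cxcl1, so their rank is uncertain. The Stfa1 call was lost without the 6 libraries of high hair follicle level (edgeR adjusted p = 0.082, the highest of 27 alternatives that began at 3.78e-08). That fit kept only libraries 3 and 4 of PMA_ethanol, so the loss may be one of power. Il24, also without a control read, was at least 621-fold higher (9.28 in log2, just below the fold change of Il6), all against a floor of 3 reads over the group. The control mean of Il6 was itself close to that floor, so its fold change carries a large counting error too. Cxcl3 had 1 control read and a ratio of 934 (95% interval 167 to 36900, counting error only). Lpo also had 1 control read, with a ratio of 1010 (95% interval 182 to 40100, counting error only). Both intervals reach below the folds of Il6, Il1b and Cxcl1, so the ranks of Il24, Cxcl3 and Lpo are uncertain too. Among the largest falls Cyp2w1, a cytochrome P450 gene, changed by -4.93 (SE 0.532, edgeR adjusted p = 3.31e-07), and Npbwr1, a neuropeptide receptor gene, by -4.62 (SE 0.258, edgeR adjusted p = 1e-10). With upper-quartile scaling the numbers of genes that rose and fell were 3682 and 7262, so that 33.6% of the called genes rose against 47.5% with TMM. That scaling shifted the median fold change by -0.236.

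**Figure D2:**
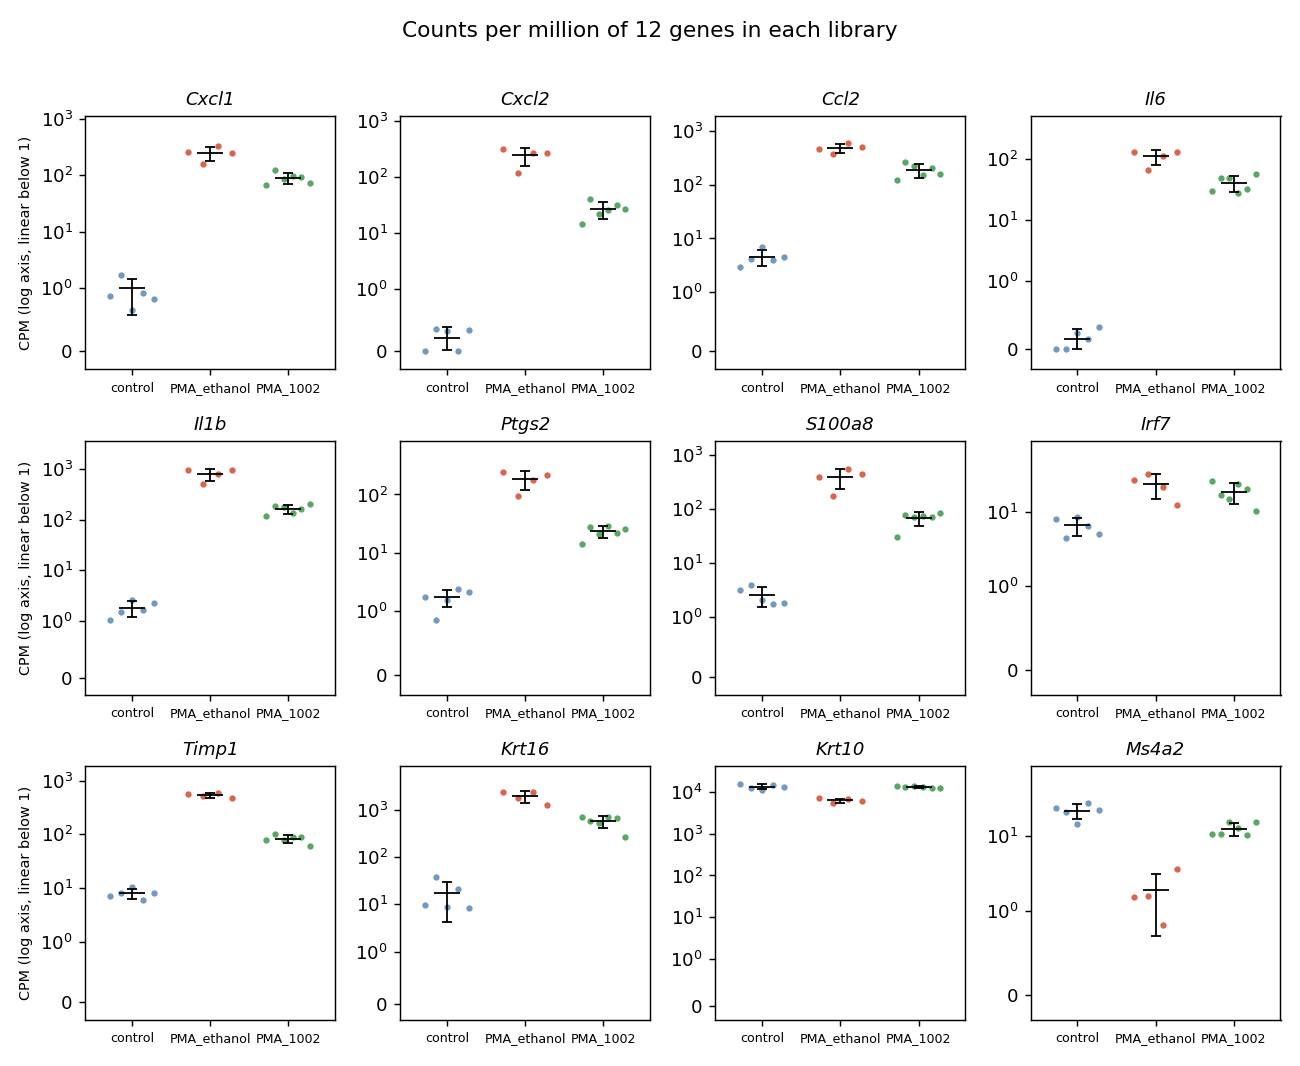
CPM of 12 genes (y axis, log scale above 1 and linear below) in each library (points) of control, PMA_ethanol and PMA_1002, with the mean and SD of each group in black. Mean Cxcl1 was 0.995 CPM in control, 246 in PMA_ethanol and 90.7 in PMA_1002, and mean Krt10 was 13320, 6210 and 13150.

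PMA_1002 versus PMA_ethanol asked what differed between inflamed ears with and without the peptide. The label of PMA_1002 does not name ethanol, so a difference in vehicle cannot be told apart from the peptide. Cxcl2, Cxcl1, Ptgs2 and Il1b were lower with the peptide, and Krt10 was higher. Cxcl2, a neutrophil-attracting chemokine like Cxcl1, went from 240 ± 85.3 CPM in PMA_ethanol (n = 4) to 26.3 ± 8.8 in PMA_1002 (n = 6), a log2 fold change of -3.17 (SE 0.286, edgeR adjusted p = 2.17e-06), and Cxcl1 from 246 ± 69.5 to 90.7 ± 20.6 CPM, by -1.43 (SE 0.187, edgeR adjusted p = 3.24e-05). Ptgs2 fell from 185 ± 66.1 to 23.1 ± 5.42 CPM, by -3.01 (SE 0.24, edgeR adjusted p = 4.56e-07), and Il1b by -2.28 (SE 0.186, edgeR adjusted p = 3.43e-07). Krt10 rose from 6210 ± 692 to 13150 ± 767 CPM, by 1.08 (SE 0.109, edgeR adjusted p = 1.36e-06). In all, 2553 genes rose and 2691 fell, 35% of those tested, of which 386 and 742 changed by a fold of at least 2.

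Other cytokine, alarmin and keratin genes changed too. Ccl2 fell by 1.37 (SE 0.202, edgeR adjusted p = 9.9e-05), Il6 fell by 1.46 (SE 0.227, edgeR adjusted p = 0.000164) and Tnf, the tumor necrosis factor gene, fell by 0.98 (SE 0.24, edgeR adjusted p = 0.00444). Csf3, the granulocyte growth factor gene, changed by -2.73 (SE 0.375, edgeR adjusted p = 2.92e-05), S100a8 by -2.52 (SE 0.306, edgeR adjusted p = 3.16e-05), S100a9 by -2.57 (SE 0.281, edgeR adjusted p = 1.06e-05), Krt6a by -1.35 (SE 0.261, edgeR adjusted p = 0.00114) and Krt16 by -1.76 (SE 0.386, edgeR adjusted p = 0.00331). Irf8, a factor of myeloid development, fell by 1.05 (SE 0.217, edgeR adjusted p = 0.00133). Irf7 (-0.33, SE 0.266, edgeR adjusted p = 0.364) and Mpo (0.00, SE 0.261, edgeR adjusted p = 0.998) did not pass the test.

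Inflammatory lists fell with the peptide. All 21 NF-kB targets fell (21 adjusted over the list alone), by a median of -0.78, with Nfkb1 at -1.22 (SE 0.0988, edgeR adjusted p = 1.51e-07). Of 26 cytokine genes 21 fell (23 adjusted over the list alone), with Hbegf, a growth factor, at -1.97 (SE 0.122, edgeR adjusted p = 1.89e-08). Of 24 chemokine genes 17 fell (19 adjusted over the list alone) and 1, Ccl12, named after its value was seen, rose by 0.59 (SE 0.191, edgeR adjusted p = 0.0232). Of 18 neutrophil genes 15 fell (15 adjusted over the list alone), with Trem1, an amplifying receptor of myeloid cells, at -2.68 (SE 0.244, edgeR adjusted p = 1.5e-06). The AP-1 list had 20 of 26 members lower (21 adjusted over the list alone), the receptor list 15 of 21 lower and 1 higher (15 and 1), the wound and alarmin list 21 of 28 lower (26) and the pattern recognition list 15 of 24 lower and 3 higher (15 and 4). Protease and matrix remodelling genes fell in 21 of 23 cases (22 adjusted over the list alone), with Timp1 at -2.69 (SE 0.132, edgeR adjusted p = 2.35e-09) and Mmp9, a gelatinase, at -2.49 (SE 0.167, edgeR adjusted p = 4.2e-08), and 11 of 14 endothelial activation and adhesion genes fell (11 adjusted over the list alone).

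The levels of these 10 lists were lower with PMA_1002 (exact permutation adjusted p = 0.0114, the smallest reached, for all but the wound list at 0.0185). Camera called 5 of them lower with either correlation, the protease list (adjusted p = 0.00671 with an estimated correlation), the neutrophil and adhesion lists (adjusted p = 0.0165 with an estimated correlation for both) and the cytokine and pattern recognition lists (adjusted p = 0.0399 with an estimated correlation for both). Its calls of the other 5 were lost, with adjusted p = 0.0525 with an estimated correlation for the chemokine and receptor lists, adjusted p = 0.055 with an estimated correlation for NF-kB, adjusted p = 0.0794 with an estimated correlation for AP-1 and adjusted p = 0.167 with an estimated correlation for the wound list.

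Interferon and leukocyte lists were lower in part. Of all 14991 genes, 35% were called in this comparison, 2691 lower and 2553 higher. The interferon-gamma list did not exceed that share, so its number of called members does not set it apart. Of 29 type I interferon-stimulated genes 15 fell (15 adjusted over the list alone; camera adjusted p = 0.229 with an estimated correlation), with Oasl2 at -1.92 (SE 0.208, edgeR adjusted p = 2.72e-06) and Isg15, a ubiquitin-like protein, at -1.78 (SE 0.253, edgeR adjusted p = 4.13e-05). Of 25 interferon-gamma genes 7 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.378 with an estimated correlation). The gene that rose, Ciita, was named after its value was seen. Of 18 T and NK cell genes 9 fell (9 adjusted over the list alone; camera adjusted p = 0.167 with an estimated correlation), with Gzmb, a cytotoxic protease, at -3.08 (SE 0.227, edgeR adjusted p = 1.12e-07). Of 25 monocyte and macrophage genes 18 fell and 2 rose (19 and 2 adjusted over the list alone; camera adjusted p = 0.167 with an estimated correlation), with Cd14, the lipopolysaccharide co-receptor, at -2.45 (SE 0.168, edgeR adjusted p = 6.25e-08). The 2 that rose, C1qa and C1qc, were named after their values were seen. The oxidant list had 10 of 24 members lower and 4 higher (11 and 5 adjusted over the list alone; camera adjusted p = 0.0794 with an estimated correlation). The exact permutation adjusted p-values of the levels were 0.0261, 0.0388, 0.0185, 0.0114 and 0.0114 in this order of lists. In the eicosanoid list 7 of 23 members fell and 4 rose (7 and 4 adjusted over the list alone; camera adjusted p = 0.168), its median of -0.03 turned to 0.05 with upper-quartile scaling, and its level was lower with the peptide (exact permutation adjusted p = 0.0114).

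Some members of the terminal differentiation, mast cell, Schwann cell and melanocyte, and cell cycle lists were higher with the peptide. Among all 14991 genes, 2553 were higher and 2691 lower, together 35%, a share that the cell cycle list did not exceed. In the terminal differentiation list 13 of 32 members rose and 5 fell (14 and 5 adjusted over the list alone), with Krt2, a keratin of the upper epidermis, at 1.09 (SE 0.108, edgeR adjusted p = 1.12e-06) and Tgm3, a transglutaminase, at -1.93 (SE 0.2, edgeR adjusted p = 3.98e-06). Camera called the list higher (adjusted p = 0.0016, and adjusted p = 0.546 with an estimated correlation), and its level did not pass the exact permutation test (adjusted p = 0.105). Of 13 mast cell genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.169), with Ms4a2 at 2.64 (SE 0.279, edgeR adjusted p = 2.12e-06) and Hdc, the one that fell, at -1.45 (SE 0.14, edgeR adjusted p = 1.06e-06). Kit and Gata2 were 2 of those that rose and were named after their values were seen. Mrgprb2, a receptor of connective tissue mast cells, rose by 2.13 (SE 0.489, edgeR adjusted p = 0.00272), a call lost at the depth of the shallowest library (edgeR adjusted p = 0.262, in a range of 0.000626 to 0.262 over 27 alternatives). Of 17 Schwann cell and melanocyte genes 6 rose (9 adjusted over the list alone; camera adjusted p = 0.113) and Egr2 fell by 0.91 (SE 0.0639, edgeR adjusted p = 4.11e-08). Of 22 cell cycle genes 6 rose (9 adjusted over the list alone, and 10 over all genes with upper-quartile scaling; camera adjusted p = 0.0181, and adjusted p = 0.546 with an estimated correlation), with Mcm6, a helicase subunit, at 0.61 (SE 0.101, edgeR adjusted p = 0.000181), and 1, Rrm2, fell. The levels of the last 3 lists were higher (exact permutation adjusted p = 0.0114, 0.0185 and 0.0328).

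The largest falls by the fixed rule were those of Il24 (-4.55, SE 0.436, edgeR adjusted p = 2.36e-05), Cxcl5, Cxcl3, Il19, Mmp13, Stfa2, Cxcl2 and Gzmb. The largest rises were those of Slc16a14 (3.56, SE 0.257, edgeR adjusted p = 5.49e-08), Npbwr1, Ms4a2, Tppp, Phyhip, P2ry4, Hlf and S1pr5. Hair follicle levels were 3.49 ± 3.22 log2 CPM in PMA_ethanol and 1.65 ± 2.45 in PMA_1002, and 0 of 26 members passed the edgeR test (1 lower at an unadjusted p under 0.05, and 1 lower with DESeq2). Camera called that list lower (adjusted p = 0.000234, and adjusted p = 0.546 with an estimated correlation), but the exact permutation test of its level did not (adjusted p = 0.372). Without the 6 libraries of hair follicle level above 4 log2 CPM, a choice made after the data were seen, 1164 genes rose and 1709 fell. That fit kept only libraries 3, the shallowest, and 4 of PMA_ethanol, so it also had less power. With upper-quartile scaling 3432 genes rose and 2118 fell, 61.8% of called genes against 48.7% with TMM.

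**Figure D3:**
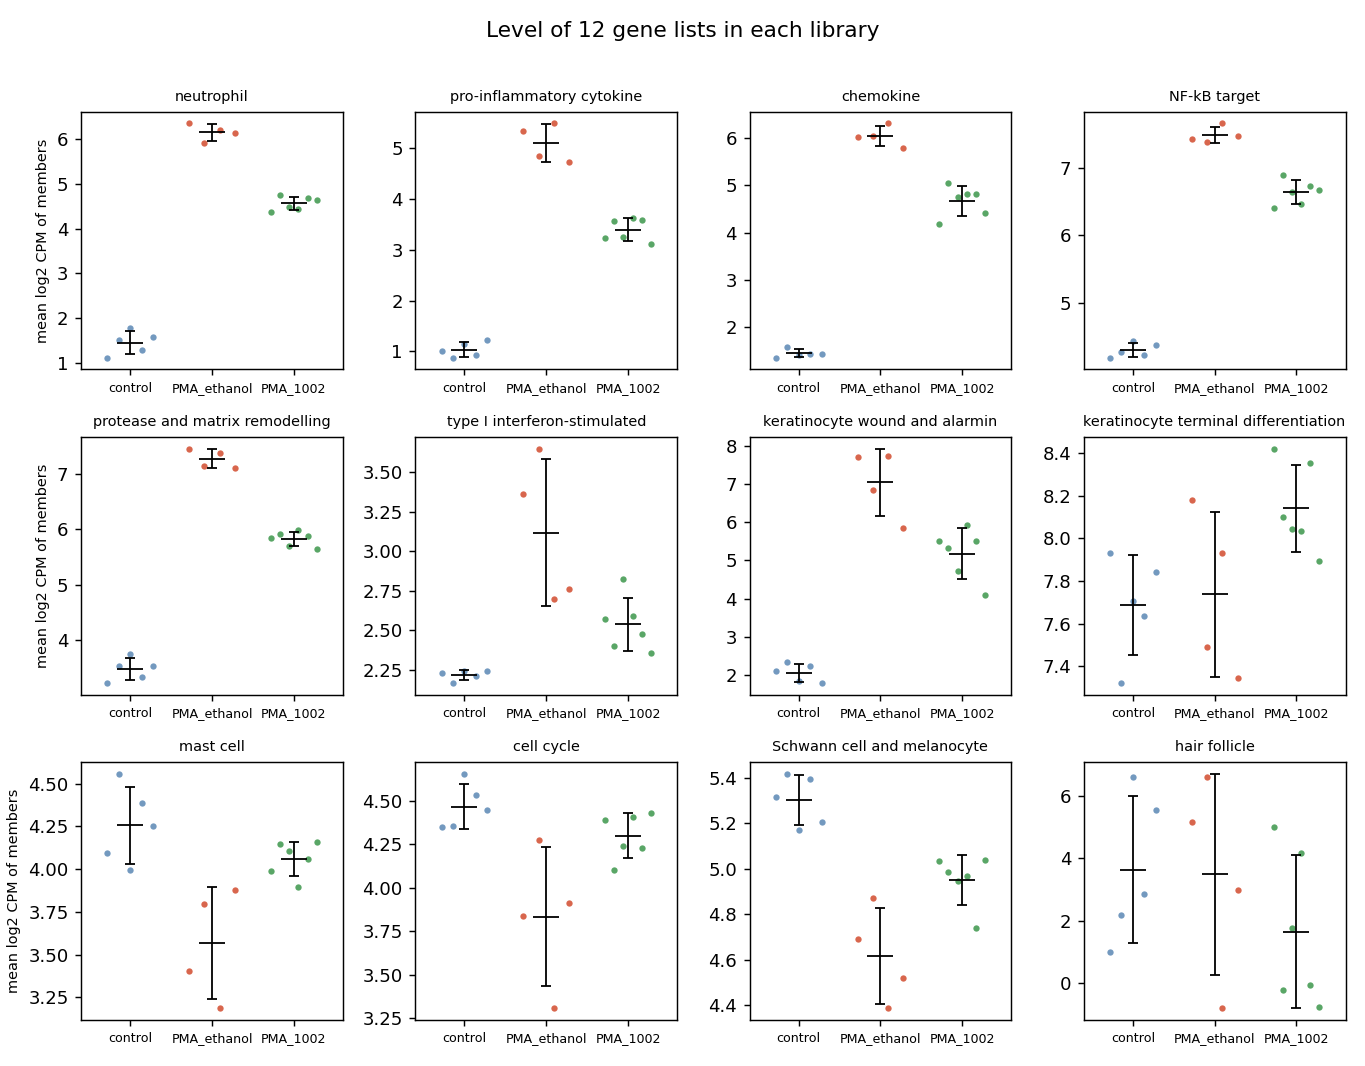
Mean log2 CPM of the measured members of 12 gene lists (y axis, with its own range in each panel) in each library (points) of control, PMA_ethanol and PMA_1002, with group means and SD in black. The neutrophil level was 1.45 ± 0.258 in control, 6.16 ± 0.179 in PMA_ethanol and 4.57 ± 0.152 in PMA_1002.

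PMA_1002 versus control asked what remained different from control in ears with PMA and the peptide. Il6, Cxcl1 and Il1b were above control. Il6 was at 40.7 ± 12.1 CPM in PMA_1002 (n = 6) against 0.145 ± 0.146 in control (n = 5), a log2 fold change of 7.85 (SE 0.444, edgeR adjusted p = 2.03e-09). Cxcl1 differed by 6.58 (SE 0.301, edgeR adjusted p = 2.03e-10), Il1b by 6.39 (SE 0.267, edgeR adjusted p = 5.23e-11) and Ptgs2 by 3.75 (SE 0.335, edgeR adjusted p = 3.85e-07). Krt10, at 13150 ± 767 CPM against 13320 ± 1900, did not pass the test (-0.02, SE 0.0989, edgeR adjusted p = 0.891), and neither did Irf8 (0.40, SE 0.217, edgeR adjusted p = 0.134), although it passed in 3 of 27 alternatives (adjusted p from 0.0135 to 0.365), among them limma-voom (adjusted p = 0.0307) and the fit without PMA_ethanol library 2 (edgeR adjusted p = 0.0392). In all, 4252 genes were higher and 3998 lower, 55% of those tested, of which 1137 and 725 differed by a fold of at least 2.

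All 24 chemokine genes and all 21 NF-kB targets were higher than in control (24 and 21 adjusted over the list alone; adjusted p = 0.0565 with an estimated correlation for both in camera). In the neutrophil list 16 of 18 were higher (16 adjusted over the list alone; camera adjusted p = 0.0565 with an estimated correlation), in the AP-1 list 24 of 26 (24 adjusted over the list alone; camera adjusted p = 0.0565 with an estimated correlation), and in the cytokine list 21 of 26 (21 adjusted over the list alone; camera adjusted p = 0.0955 with an estimated correlation). Of the protease list 20 of 23 were higher and of the adhesion list 13 of 14 (20 and 13 adjusted over the list alone; adjusted p = 0.0516 with an estimated correlation for both in camera). Of the wound and alarmin list 25 of 28 were higher (26 adjusted over the list alone; camera adjusted p = 0.371 with an estimated correlation), with Lcn2, an iron-sequestering defense protein, at 3.55 (SE 0.15, edgeR adjusted p = 1.71e-11) and Krt16 at 5.12 (SE 0.466, edgeR adjusted p = 1.05e-06). The levels of these 8 lists were higher in all 6 PMA_1002 libraries than in the controls (exact permutation adjusted p = 0.00419, the smallest reached).

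The type I interferon list had 10 of 29 members higher and 4 lower (10 and 4 adjusted over the list alone; camera adjusted p = 0.216), and its level was higher (exact permutation adjusted p = 0.00746). Irf7 was higher by 1.49 (SE 0.273, edgeR adjusted p = 0.000283). In the interferon-gamma list 18 of 25 were higher and 2 lower (18 and 2 adjusted over the list alone; camera adjusted p = 0.516 with an estimated correlation). The level of T and NK cell genes did not pass (2.11 ± 0.275 against 1.81 ± 0.237 log2 CPM, exact permutation adjusted p = 0.111), with 5 of 18 members higher and 2 lower (5 and 2 adjusted over the list alone, and 4 and 5 with upper-quartile scaling), and the median of -0.01 and mean of 0.34 of its fold changes differed in sign. Terminal differentiation genes were higher in 13 of 32 cases and lower in 0 (13 and 0 adjusted over the list alone; edgeR, with 18 and 0 at an unadjusted p under 0.05 and 17 and 0 with DESeq2), with Abca12, a lipid transporter of the skin barrier, at 1.06 (SE 0.153, edgeR adjusted p = 2.38e-05). The level of that list was higher (exact permutation adjusted p = 0.0106), and camera gave adjusted p = 0.00625 and adjusted p = 0.716 with an estimated correlation. With upper-quartile scaling 7 of its members were higher and 2 lower. Mast cell genes were lower in 7 of 13 cases and 1, Hdc, was higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.257), and the list level did not pass (exact permutation adjusted p = 0.113), with Ms4a2 at -0.80 (SE 0.207, edgeR adjusted p = 0.00344). Schwann cell and melanocyte genes were lower in 9 of 17 cases and higher in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.516 with an estimated correlation; exact permutation adjusted p = 0.00419), or 14 and 1 with upper-quartile scaling. In the cell cycle list 4 of 22 were higher and 4 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.27; exact permutation adjusted p = 0.0915), or 2 and 10 with upper-quartile scaling.

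By the same rule Fgf23, Il6, Mmp1b and Acod1 (7.26, SE 0.742, edgeR adjusted p = 3.25e-06) were named for their rises. Fgf23 was at least 70.2-fold higher against the floor of 3 reads, a bound (6.13 in log2) below the fold changes of Cxcl1 and Il1b, so its rank is uncertain. The largest falls were those of Cyp2w1 (-3.21, SE 0.374, edgeR adjusted p = 2.07e-06), P2rx2, Fggy and Pls1. With upper-quartile scaling 3079 genes were higher and 5811 lower, 34.6% of called genes against 51.5% with TMM, and the median fold change shifted by -0.158.

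Genes called in PMA_ethanol versus control and again in PMA_1002 versus PMA_ethanol mostly had opposite signs. Of genes that rose with PMA_ethanol, 2550 fell in PMA_1002 versus PMA_ethanol, and of those that fell, 2340 rose. Another 16 rose further and 11 fell further, while 2310 rising and 3031 falling genes did not pass in PMA_1002 versus PMA_ethanol. The 2 comparisons share the PMA_ethanol libraries. In 20 simulations without any effect the opposite calls averaged 0 and 0.05 genes, but there almost no gene is expected to pass in either comparison. A PMA change without a peptide effect was not simulated. Independent lists of these sizes gave 875 and 917. With the PMA_ethanol libraries split between the comparisons the medians over 6 splits were 1844 and 1416.5, against 593 and 511 for independent lists of the split sizes. Fold changes of the 2 comparisons had r = -0.828 across genes, which are not independent replicates, against a mean r of -0.595 in the simulations and a median r of -0.675 (range -0.776 to -0.55) with split libraries. Their covariance was -0.66 against a simulated -0.0428, a difference of -0.618. Of the genes with opposite calls, 3563 still differed from control in the direction of PMA_ethanol, 1290 did not pass against control and 37 were past control on the other side. Genes such as Il1b, Cxcl1 and Cxcl2 belonged to the 3563 that remained above or below control.

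Both comparisons against control called 3913 genes higher and 3676 lower. In the simulations without effect, where almost no gene is expected to pass, these counts averaged 0, and independent lists gave 1383 and 1435. With the control libraries split between the comparisons the medians over 10 splits were 3391 and 2867, against 1109 and 1027 for independent lists of the split sizes. The covariance of the fold changes was 1.01 against a simulated 0.0315, a difference of 0.979.

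Measured on libraries held out from the choice of genes, the PMA_1002 libraries kept 58.76% of the log2 change with PMA_ethanol (median over 60 splits, range 52.76% to 66.18%). Rising genes kept 61.99% and falling genes 55.79%. Single PMA_1002 libraries ranged from 44.96% to 68.09% (SD 8.68, n = 6). Among gene lists whose level differed between PMA_ethanol and control, NF-kB targets kept 73.4% ± 5.61 of their change in mean level, chemokines 70.1% ± 6.9, neutrophil genes 66.2% ± 3.24 and cytokines 58.1% ± 5.59 (n = 6 each). Type I interferon-stimulated genes kept 35.6% ± 18.6 and interferon-gamma genes 66% ± 18, T and NK cell genes 29.4% ± 27.3, mast cell genes 28.6% ± 14.7 and cell cycle genes 26.5% ± 20.5. The shares of lists were measured with the same libraries that showed the change, and differences between lists were not tested.

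**Figure D4:**
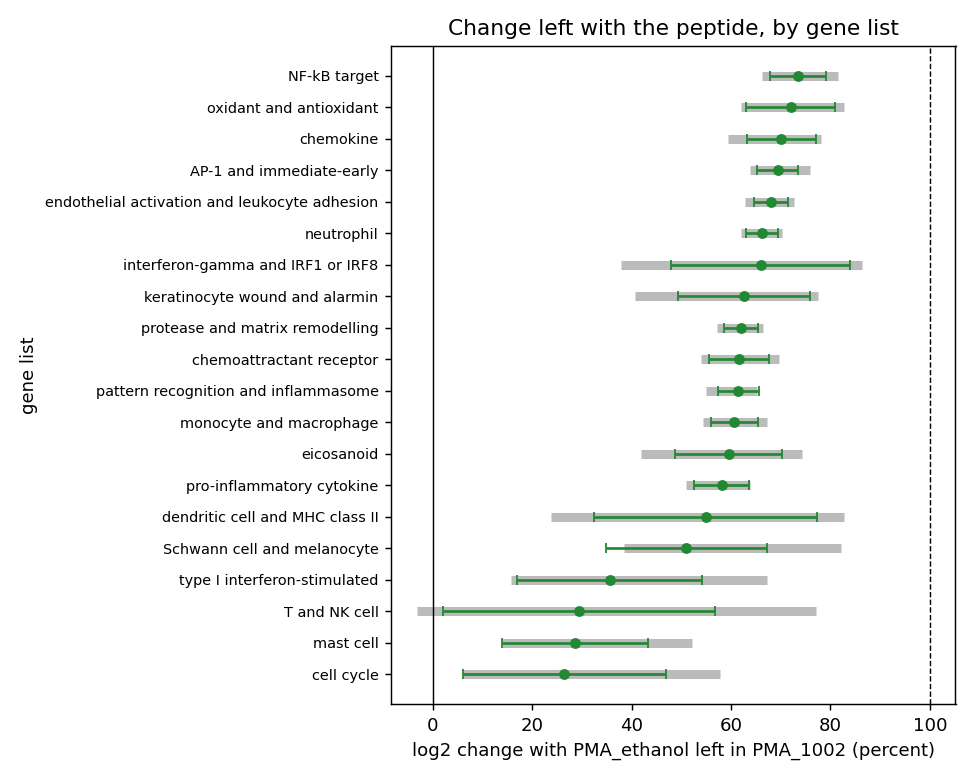
Percent of the change in mean log2 CPM with PMA_ethanol that was left in PMA_1002 (x axis) for each gene list whose level differed between PMA_ethanol and control (y axis), with the mean (point), SD (bar) and range (gray) over 6 PMA_1002 libraries. The dashed line at 100 marks the PMA_ethanol level and the line at 0 the control level, and NF-kB targets kept 73.4% against 26.5% for cell cycle genes.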

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

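The tests of an RNA mixture, of a weaker or earlier exposure, of other ear tissue and of the hair follicle level against library size were chosen after the values had been seen.

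The first pattern is that the PMA_1002 libraries lay between control and PMA_ethanol. An RNA mixture in 1 proportion per library would leave the same fraction of the linear CPM difference in rising and falling genes. A mean fraction of 0.699 was left in 2070 falling genes and 0.43 in 2072 rising genes, a difference of 0.269 (SD 0.034), which argues against such a mixture. The sign was the same in 6 of 6 libraries (two-sided exact sign-flip p = 0.0312, the smallest possible). All 6 were measured against the same control and PMA_ethanol means, in genes chosen with those libraries. The sign-flip p therefore covers only the spread among the PMA_1002 libraries. Library size as the cause is argued against by thinning to the shallowest library, after which 90.6% of the genes called with PMA_ethanol still had a PMA_1002 mean between those of the other groups. A weaker or earlier exposure to PMA in ears given the peptide stays open, since all 14 lists that camera called higher with PMA_ethanol had a lower mean level in PMA_1002. An effect of the peptide, which the design names, predicts the same and cannot be told apart from such an exposure with these data. Ethanol is named only in the label of PMA_ethanol, so a difference in vehicle cannot be told apart either.

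The second pattern is the spread of hair follicle levels within groups. Reads shared between near-identical keratin-associated protein genes are argued against by the 8 list members of other families, whose mean ranged over at least 3.86 log2 CPM within each group. A different amount of all other ear tissue would lower every other tissue list, but the fibroblast level rose with the hair follicle level (slope 0.0745, SE 0.0116, deviations from group means) while the muscle (-0.196, SE 0.0522) and adipocyte levels (-0.0963, SE 0.0203) fell. Loss of hair genes at low depth is argued against by the smallest range within a group of 4.57 after thinning to the shallowest library, whereas a relation to library size stays open (Pearson r = 0.411, permutation p = 0.128; Spearman rho = 0.371, permutation p = 0.172; 15 libraries, 100000 resamples; r = 0.564 without the 2 libraries farthest from the median depth), and no biological explanation of this spread was tested.

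Chance splits of the libraries were drawn 100 times per comparison, the real split included. For the counts of genes, 1 split of the 100, the real one, reached 10258 genes for PMA_ethanol versus control (highest other 7733). Only the real split reached 5244 for PMA_1002 versus PMA_ethanol (highest other 564) and 8250 for PMA_1002 versus control (highest other 7384). A chance split of these libraries is thus unlikely to give such counts. The labels do not say that the libraries came from separate animals, so chance between animals is not excluded. The 3 other splits of highest count for PMA_ethanol versus control set the 4 PMA_ethanol libraries and 1 control against the other controls. For the number of lists that camera called chance cannot be excluded, as 57 splits called at least the real 16 lists (highest other 24), 23 at least the real 18 (highest other 21) and 16 at least the real 17 (highest other 22).

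Single libraries stood apart from the others of their group, by the gap to the nearest library as a share of the range (Dixon's 95% value), in 21 of 369 groups of values tested, and chance gives about 1 in 20 groups. In PMA_ethanol library 3, the shallowest, the red blood cell level was 3.14 log2 CPM (others 3.73 to 3.84), the fibroblast level 8.62 (9.28 to 9.36) and Mpo 1.82 (3.44 to 3.75). In PMA_ethanol library 2, Acod1 was at 6.4 log2 CPM (others 7.86 to 8.08) and Csf3 at 2.49 (3.5 to 3.61), while Fgf23 at 4.5 (3.37 to 3.54), Fggy at 2.43 (0.0583 to 0.278) and Irf8 at 5.58 (4.42 to 4.61) lay above the others. In PMA_1002 library 5, the deepest with 28585995 reads in genes (28.6 M, others 4.96 to 10.1 M), the Schwann cell and melanocyte level was 4.74 (4.94 to 5.04) and Fgf23 1.24 (2.81 to 3.72). In PMA_1002 library 1, S100a8 was at 4.91 (6.13 to 6.43) and S100a9 at 5.98 (6.95 to 7.42), and in library 6 Krt16 was at 8.08 (9.05 to 9.52). Control library 3 had 11501228 reads in genes (11.5 M, others 5.37 to 6.04 M), with Mrgprb2 at 1.25 (2.47 to 2.84) and, near the floor of the scale, Il19 at -2.24 (-1.45 to -1.38) and Lpo and Mmp1b at -1.78 (-2.24 in the others). Cxcl3 was at -1.38 in control library 2 (-2.24 in the others) and Ngfr at 3.71 in control library 1 (4.02 to 4.13).

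Reads given to no gene were not used in the comparisons. As shares of all reads in a table, those outside annotated features made up 11.82% with PMA_ethanol against 11.34% in control (exact permutation p = 0.0238), and those with several positions 19.16% against 17.09% (exact permutation p = 0.00794, the smallest possible).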

How the results depend on the processing

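Thinning and leaving out the 6 libraries of hair follicle level above 4 log2 CPM were tests chosen after the data had been seen. No called result turned its direction. Of 324 results of named genes, 293 had no change of call in any alternative, and 31 had one in at least 1. Many of these genes were named for a small p or a large change, so this does not measure the stability of all calls. Of all genes called for PMA_1002 versus PMA_ethanol, 51.4% were called again without the 6 libraries, 70.5% after thinning and 74.3% with the replicate block. Counts of genes stayed within 1.5 times under all other alternatives, with these exceptions. A minimum fold of 1.5 left 1186 higher and 1379 lower genes for PMA_1002 versus PMA_ethanol and 2185 and 2154 for PMA_1002 versus control, by construction. Without the 6 libraries, PMA_1002 versus PMA_ethanol had 1164 and 1709, with 9 libraries in the fit. The 6 were control 3 and 5, PMA_ethanol 1 and 2, and PMA_1002 1 and 4. PMA_ethanol thus kept only libraries 3, the shallowest, and 4. A loss of power cannot be told apart here from a dependence on hair follicle content. At an adjusted p of 0.1, 30 genes rose in both PMA_ethanol versus control and PMA_1002 versus PMA_ethanol, and 17 fell in both, against 16 and 11 at 0.05. At 0.1, 30 genes were higher than control with PMA_ethanol and lower with PMA_1002, and 44 the reverse, against 13 and 24 at 0.05. Splitting the control libraries gave medians of 8 and 18 for these 2 counts. Splitting the PMA_ethanol libraries gave a median of 1416.5 genes that fell and then rose, with fewer libraries per comparison. Camera with an estimated correlation called 2 lists (2 higher, 0 lower) for PMA_ethanol versus control, 5 (0 and 5) for PMA_1002 versus PMA_ethanol and 0 (0 and 0) for PMA_1002 versus control, against 16, 18 and 17 with the preset correlation. Fry, which tests no contrast with other genes, called 5 lists lower for PMA_ethanol versus control and 1 higher for PMA_1002 versus PMA_ethanol, and its mixed test called 26 in each comparison with control. Leaving out each library gave 1 to 3 lists lower for PMA_ethanol versus control (1 without PMA_ethanol 1 or PMA_1002 3), 1 to 4 higher for PMA_1002 versus PMA_ethanol (1 without PMA_ethanol 1, 4 without PMA_ethanol 4) and 1 to 3 lower for PMA_1002 versus control (1 without PMA_1002 5); the cause was not tested. The replicate block gave 4704 and 5158, 1890 and 2098, and 4108 and 3699 genes higher and lower in the 3 comparisons, and 4 lists higher for PMA_1002 versus PMA_ethanol against 2 without it. The numbers do not pair the libraries: 2 of 13 pairs of the same number correlated over 0.1 (r from -0.533 to 0.579), and 1 library correlated best with its own number. Thinning to 2656680 reads per library gave 4111 and 4551, 1854 and 2102, and 3411 and 3154 genes, so depth limits how many genes are called.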

Other observations

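The genes named in the next paragraph, the tests against both other groups with their simulations, and Ighm were chosen after their values were seen.

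Some genes did not follow the axis between control and PMA_ethanol. Without a call in PMA_ethanol versus control, 92 genes were higher and 56 lower in PMA_1002 than in both other groups. These comparisons share the PMA_1002 libraries. In 20 simulations without effect, where almost no gene is expected to pass, the counts averaged 0 and 0. With each gene at the estimated share of its change, 20 simulations averaged 4.3 and 3.1, and independent lists gave 13.1 and 8.49. With the PMA_1002 libraries split between the comparisons the medians over 20 splits were 46.5 and 20. Tph1, an enzyme of serotonin synthesis (chromosome 7 from 46644641 to 46672537 on GRCm38), was at 12.7 ± 4.37 CPM in control, 12.8 ± 3.08 in PMA_ethanol and 34.6 ± 3.13 in PMA_1002, with log2 fold changes of 1.42 (SE 0.216, edgeR adjusted p = 9.36e-05) against PMA_ethanol and 1.43 (SE 0.199, edgeR adjusted p = 1.75e-05) against control. Ngfr, a neurotrophin receptor, went from 15.9 ± 1.78 and 17.9 ± 1.79 to 37 ± 5.2 CPM (1.06 against PMA_ethanol, edgeR adjusted p = 3.73e-06). Itgb4, an integrin chain of hemidesmosomes, Wnt10a, a Wnt ligand, and Evpl, a protein of the cornified envelope, were higher by 0.54, 0.56 and 0.58 (edgeR adjusted p = 2e-04, 0.00039 and 0.000724). Slco2b1, a transporter, was lower than in both other groups (-1.63 against PMA_ethanol, edgeR adjusted p = 6.71e-05, and -1.15 against control, edgeR adjusted p = 0.000473). All 6 were called against both groups in 12 of 12 alternatives, which do not include the fits that left out each library in turn. Slc27a3 and Pla2g4f fell with PMA_ethanol and rose above control with the peptide (0.69 and 0.57 against control, edgeR adjusted p = 0.000326 and 0.000169). Ddit4, a stress-response gene, fell by 0.39 with PMA_ethanol (edgeR adjusted p = 1e-04) and by 0.61 more with the peptide (edgeR adjusted p = 3.17e-06). No test of the cause of these values was made.

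Structural and resident cell lists moved in part. Among all 14991 genes, 68.4% were called for PMA_ethanol versus control and 55% for PMA_1002 versus control. With TMM scaling each list below had a smaller share of called members, so these counts do not set the lists apart. Of 18 cartilage genes 8 were lower and 1 higher in PMA_1002 than in control (7 and 1 adjusted over the list alone; 12 and 0 with upper-quartile scaling; camera adjusted p = 0.0129, and adjusted p = 0.383 with an estimated correlation; exact permutation adjusted p = 0.00746), with Col9a2, a cartilage collagen, at -0.75 (SE 0.0958, edgeR adjusted p = 5.37e-06). In PMA_ethanol 5 cartilage genes were already lower and 1 higher than in control. Between PMA_1002 and PMA_ethanol 0 passed edgeR, with 3 lower at an unadjusted p under 0.05 and 1 lower with DESeq2. Adipocyte genes fell in 6 of 17 cases with PMA_ethanol (6 adjusted over the list alone, and 11 with upper-quartile scaling; camera adjusted p = 0.0646, exact permutation adjusted p = 0.0586), with Thrsp, a lipogenic gene, at -3.22 (SE 0.468, edgeR adjusted p = 1.14e-05). Of 18 sebaceous gland genes 8 fell and 3 rose (8 and 3 adjusted over the list alone; camera adjusted p = 0.321; exact permutation adjusted p = 0.0895). Of 23 fibroblast genes 7 fell and 4 rose (5 and 4 adjusted over the list alone, and 13 and 1 with upper-quartile scaling; camera adjusted p = 0.42; exact permutation adjusted p = 0.42), with Pdgfra at 1.26 (SE 0.0725, edgeR adjusted p = 1.5e-10). Among 16 endothelial identity genes 4 rose and 4 fell (4 and 4 adjusted over the list alone, and 3 and 8 with upper-quartile scaling; camera adjusted p = 0.907; exact permutation adjusted p = 0.828; median -0.07, mean 0.03), with Flt1, a receptor of vascular growth factors, at 2.29 (SE 0.128, edgeR adjusted p = 1.01e-10). Of 17 dendritic cell and MHC class II genes 6 rose and 5 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.484) and the list level was higher (exact permutation adjusted p = 0.0123), with Cd209a, a lectin of dendritic cells, at 2.99 (SE 0.184, edgeR adjusted p = 4.4e-10), and the median of 0.12 turned to -0.12 with upper-quartile scaling. Of 2 measured B cell genes Ighm passed the test at -0.56 (SE 0.23, edgeR adjusted p = 0.0411; 0 adjusted over the list alone; exact permutation adjusted p = 0.531 for the level). The Ighm call was lost in 13 of 27 alternatives (adjusted p from 0.00158 to 0.113), among them DESeq2 and the fits without control 1, 3 or 5, PMA_ethanol 1, 3 or 4, or PMA_1002 1 or 6. Of 6 red blood cell genes 1 fell (1 adjusted over the list alone; exact permutation adjusted p = 0.826; median 0.11, mean -0.06, and a median of -0.12 with upper-quartile scaling). In the skeletal muscle and mitochondrially encoded lists 0 of 25 and 0 of 7 members passed edgeR with PMA_ethanol, with 0 and 0 at an unadjusted p under 0.05 and 0 and 0 with DESeq2, but 1 and 2 fell with upper-quartile scaling. Among the muscle genes Myh8 did not pass (edgeR adjusted p = 0.0811) but was called lower in 6 of 27 alternatives (adjusted p from 0.0122 to 0.596), which were upper-quartile scaling, limma-voom, the fit on the 2 groups alone, the fit with covariates and those without PMA_1002 1 or 2. Myot was called in 1, with the covariates (edgeR adjusted p = 0.00297, in a range up to 0.733).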
